A study of Arabidopsis thaliana with 6 samples.

How the data were processed

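Transcript levels were measured in root tips of Arabidopsis thaliana seedlings aged 7 days, on 6 Affymetrix ATH1 arrays with 1 array per sample. The labels gave 3 groups of 2 arrays: untreated roots at 0 min, untreated roots at 120 min, and roots labelled as gibberellin (GA) treated at 120 min. Groups and replicate numbers were taken from the sample titles. The treated samples also carried the source name GA2oxOE1I and a gene knock out label that the untreated Col-0 samples lacked, so a difference in plant line and the treatment cannot be told apart here. Nothing in the labels said that replicates came from separate cultures, so the p-values measure the spread between these arrays, part of which may be technical.

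Per the labels' protocols, biotin-labelled target was made from total RNA with a one-cycle labelling kit. MAS5 and GCOS were named in the submitters' processing notes, without versions or roles, and no genome build was given in the sources used here. The deposited values were linear MAS5 intensity per probe set. The mean after leaving out the lowest and highest 2% of values was 100.0 on every array, and no log or quantile step was seen in the deposited intensity values. MAS5 summarises each probe set on each array by itself, which makes low signals noisy. Detection calls were not used here, and the number of arrays limits the precision.

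The table held 22810 probe sets, of which 64 were array controls and were used only to describe array quality. The other 22746 were taken to log2(signal + 16), so differences of dim genes are understated. A probe set was tested when its mean over all 6 arrays lay above the 40th percentile, which corresponded to a signal of 24.4 and left 13647 probe sets. Gene names came from a platform annotation dated 2016, updated through gene identifiers with the RefSeq table of assembly TAIR10.1, which was used for names and for plastid membership only. Of the 22746 probe sets, 13513 matched 1 gene, 503 matched several and 8730 were not listed in that annotation. The identifiers of 13436 of the 13513 were matched in the RefSeq table. Probe sets without a name entered the tests and the counts, and no coordinates are printed.

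Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), with all 3 groups in 1 fit, 3 residual degrees of freedom and 5.80 prior degrees of freedom. Tests were two-sided and adjusted by the Benjamini-Hochberg method over the tested probe sets, at a threshold of 0.05. Before the data were examined, 30 gene lists with 347 genes were fixed. A probe set was named for 60 of these genes, and 35 genes were tested. Of the 30 lists, 13 had no named probe set, 3 had only probe sets below the filter, 8 had 1 or 2 tested members and were given as values, and 6 had at least 3 tested members. These 6 were tested with camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation, and with fry, each adjusted over the 6 lists of a comparison.

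Genes were named by a rule fixed before the data were examined. Only probe sets matching 1 gene were used, and a gene with several was given by the brightest. For the treated and for the time comparison, up to 12 genes in each direction were to be taken from those past the threshold whose groups did not overlap. Since none passed, 24 genes with the smallest unadjusted p and groups that did not overlap were named as values. For the treated roots against untreated roots at 0 min, the 4 largest differences in each direction with groups that did not overlap were named, again as values. Up to 4 members of each list and every measured member of the gibberellin perception list were added, of which GID1C and SLY2 lay below the filter and were given as signals only.

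The fit was tested on simulated data with the real means, spread and replicate offsets of 13647 probe sets, for the treated against the untreated roots at 120 min. In 10 draws with 200 changed probe sets, a log2 change of 1 was recovered in 1.6% of cases, 1.5 in 38.2%, 2 in 76.6% and 3 in 97.2%, with 0.2 false calls per draw. With the replicate number as a block the recovery was 59.2%, 92.2%, 98.6% and 100%, with 18.4 false calls per draw. These false calls were a larger share of all calls than the threshold of 0.05 aims at. The draws used the offset as estimated, which holds noise and so favours the block over the fit without it. They also gave all arrays the same spread, while the SD of the replicate difference was 0.60 in treated and 0.40 in 0 min roots. Random sets of 6 unchanged probe sets passed an unadjusted camera p of 0.05 in 4.6% of cases, and sets shifted by 0.5 passed in 99.6%. The noise was drawn independently for each probe set. In the real data the estimated correlation was 0.342 within the alpha-expansins and 0.859 within the GA perception list. The 4.6% and 99.6% therefore do not describe the camera test on such lists. Another 50 draws without any change, made from the estimated replicate offset and 1 spread per probe set for all arrays, gave chance values for the unadjusted counts and for groups that do not overlap. Their noise was independent between probe sets as well, so their ranges leave out any variation that probe sets share. The estimated offset holds noise as well, so it is overstated in these draws, and 50 more used it at 0.82 of its size, which leaves out the variance that noise gives.

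Alternatives fixed before the data were examined were other pseudocounts and filters, quantile normalization, median centring, eBayes without a trend or with robust estimation, the replicate number as a block, a fit of the 2 compared groups alone, 1 probe set per gene, an estimated correlation within lists, and each array left out in turn. Array weights were added after the data had been seen, as was a screen of gene families by symbol and of plastid-encoded genes. The grouping of that screen, which first also used older gene names, was narrowed after its first result was seen.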

Results

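The data set held 6 ATH1 arrays of Arabidopsis root tips from seedlings aged 7 days, grown on sucrose-containing plates in continuous light. There were 2 arrays of untreated roots at 0 min, 2 of untreated roots at 120 min and 2 of roots labelled as gibberellin treated at 120 min. Gibberellin (GA) is a plant hormone that promotes growth by releasing the repression exerted by DELLA proteins. The series title named GA treatment of root tips as its subject. The treated samples carried another source name than the untreated Col-0 samples, so each difference below between treated and untreated roots is one between samples that may also differ in plant line. No GA 2-oxidase or GA biosynthesis gene had a named probe set, so the plant line was not checked on these genes.

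Array quality differed with the replicate number and most on the first treated array. The 3' to 5' signal ratio of actin was 14.8 on treated replicate 1, against 4.94 and 4.44 on untreated replicate 1 at 0 and 120 min and 2.22 to 2.52 on the 3 replicate 2 arrays. The ratio of GAPDH was 1.755 on treated replicate 1 and 0.759 to 1.36 on the other 5 arrays, and that of ubiquitin was 1.80 against 0.859 to 1.14. The control probe set for 25S ribosomal RNA read 61.3 on treated replicate 1 and 812 to 5288 on the other 5 arrays. The geometric mean of 9 hybridisation spike probe sets was 1711, 1276 and 2482 on the replicate 1 arrays and 749, 829.6 and 1003 on the replicate 2 arrays, in the order untreated 0 min, untreated 120 min and treated. Across the 13647 tested probe sets, replicates correlated at 0.958 in the untreated 0 min group, 0.945 in the untreated 120 min group and 0.907 in the treated group. The SD of the replicate difference in log2 was 0.40, 0.46 and 0.60 in the same order. Probe sets are not independent replicates.

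**Figure D1:**
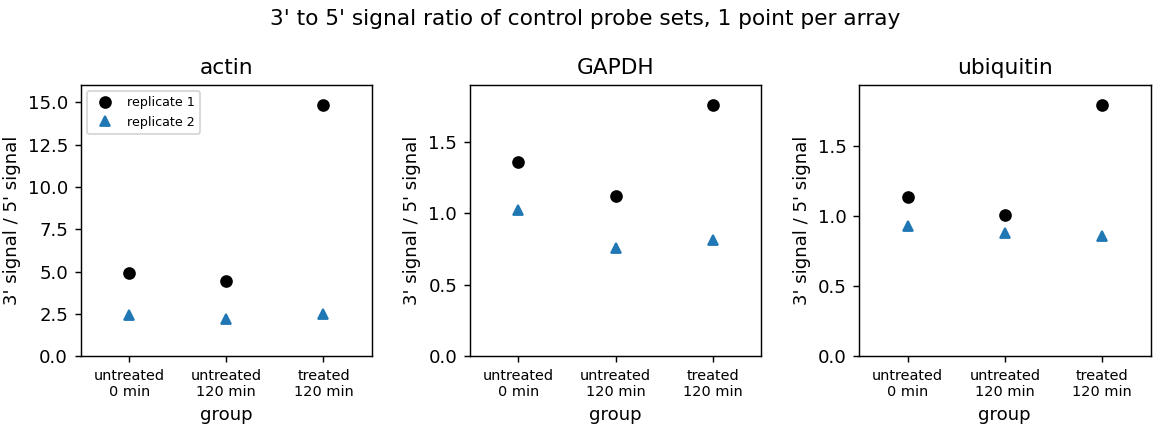
Ratio of 3' to 5' signal (vertical axis, no unit, starting at 0) of the control probe sets for actin, GAPDH and ubiquitin in the 3 groups, with 1 point per array, circles for replicate 1 and triangles for replicate 2. Treated replicate 1 had the highest ratio for each gene, 14.8, 1.755 and 1.80.

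The first comparison asked which transcripts differed between GA-treated and untreated roots at 120 min. All 6 tested alpha-expansins, proteins that loosen the plant cell wall, had lower mean log2 signals in treated roots, by 0.33 on average. EXPA9 read 326 ± 134 in treated and 490.5 ± 6.77 in untreated roots, EXPA7 read 226 ± 72.5 and 294 ± 27.8, EXPA15 read 156 ± 47.8 and 228 ± 145, and EXPA18 read 262 ± 17.2 and 302 ± 23.4 (SD, n = 2 for each). The log2 differences of EXPA20 and EXPA4 were -0.36 and -0.031. The other 2 measured members lay below the signal filter and were not tested: EXPA8 read 5.22 and 2.43 in treated and 2.68 and 2.72 in untreated roots, and EXPA16 read 4.62 and 7.05 against 9.33 and 3.07. The list fell by the camera test (adjusted p = 0.0281), while 0 of the 6 members passed by themselves in limma, over all probe sets or adjusted over the list alone. The call was lost with an estimated correlation (adjusted p = 0.553), and fry gave an adjusted p of 0.699. It also rested on treated replicate 1, the array with the highest 3' to 5' ratios: without it the mean was -0.018 (adjusted p = 0.572), and without untreated 120 min replicate 2 it was 0.024 (adjusted p = 0.849). Pseudocount 1, no filter, quantile normalization and median centring gave adjusted p-values of 0.0647, 0.128, 0.069 and 0.0535.

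**Figure D2:**
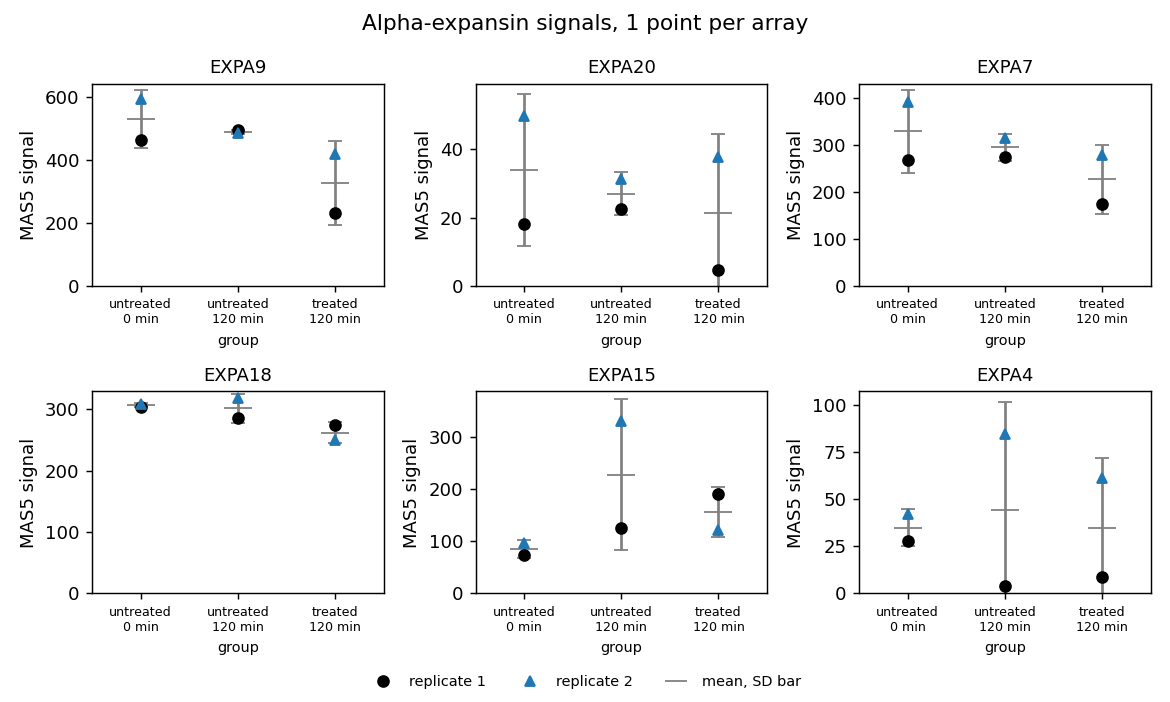
MAS5 signal (vertical axes, linear, starting at 0) of the 6 tested alpha-expansins in the 3 groups, with 1 point per array and a bar for the mean and SD of 2 arrays, drawn down to 0 where the SD exceeds the mean. EXPA9 read 232 and 421 on the treated arrays and 495 and 486 on the untreated arrays at 120 min.

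For each of the 3 tested genes of GA perception, the treated arrays lay on opposite sides of both untreated arrays at 120 min. GID1B, a GA receptor, read 4.87 on treated replicate 1 and 214 on treated replicate 2, against 101 and 73.0 in untreated roots at 120 min. GID1A, a related receptor, read 19.7 and 60.9 in treated and 46.4 and 47.2 in untreated roots. SLY1, the F-box protein that targets DELLA proteins for breakdown, read 79.2 and 162 in treated and 136 and 107 in untreated roots. Of the members below the filter, GID1C read 7.48 and 23.8 in treated and 24.1 and 30 in untreated roots at 120 min, and SLY2 read 25.4 ± 9.78 and 19 ± 1.21. At 0 min they read 27.4 ± 2.91 and 30 ± 6.13 (SD, n = 2 for each). The perception list (GID1A, GID1B and SLY1, 0 higher and 3 lower) had a mean log2 difference of -0.30 and did not pass (camera adjusted p = 0.291). The list of genes induced by DELLA proteins (GID1A, GID1B and XERICO) had a mean of -0.29 (adjusted p = 0.291). XERICO, a RING-type zinc finger gene, read 165 ± 44.5 in treated and 174 ± 62.6 in untreated roots (SD, n = 2). Treated replicate 1 set the sign of both lists. Without it their means were 0.615 and 0.555, and without treated replicate 2 they were -1.21 and -1.14, with 1 treated array left in each case. The lists share GID1A and GID1B, so they are not separate results. The estimated correlation between genes was 0.859 and 0.694 within them, against the preset 0.01.

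Of the other lists, the XTH family of xyloglucan-modifying wall enzymes had 3 members higher and 5 lower in treated roots, with a mean of -0.12 (camera adjusted p = 0.281). XTH18 differed by -0.45, EXGT-A3 by -0.32, XTH33 by -0.24 and XTH19 by -0.14. With each array left out, XTH18 ranged from -0.85 to -0.038 and EXGT-A3 from -0.63 to -0.0038. Without treated replicate 1 the mean of the family was -0.25 (adjusted p = 0.0485), while it turned to 0.014 without treated replicate 2 (adjusted p = 0.906) and to 0.018 without untreated 120 min replicate 2 (adjusted p = 0.907). Touch and wound response genes had 2 members higher and 1 lower (mean 0.30, adjusted p = 0.232): the zinc finger gene STZ, also called ZAT10, differed by 0.57, WRKY53 by 0.44 and the calmodulin-like CML38 by -0.10. Without treated replicate 1 that mean was 0.50 (adjusted p = 0.0227), without treated replicate 2 it was 0.101 (adjusted p = 0.906) and without untreated 120 min replicate 1 it was 0.133 (adjusted p = 0.792). Inhibitors of cyclin-dependent kinases had 2 members higher and 1 lower (mean 0.16, adjusted p = 0.291), with SMR2 at 0.40, SMR3 at 0.13 and SIM at -0.060. With an estimated correlation these 3 lists each had an adjusted p of 0.553, and the perception list and the list of DELLA-induced genes each had 0.554.

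Lists with 1 or 2 tested members were given as values only, as log2 differences with 95% confidence intervals. In the GASA family of GA-regulated peptides, GASA7 differed by 0.056 (-0.65 to 0.76) and GASA10 by 0.052 (-0.66 to 0.77), and GASA10 turned sign under quantile normalization and both under median centring. The Aurora kinases AUR1 and AUR2, markers of mitosis, differed by 0.16 (-0.38 to 0.71) and 0.20 (-0.45 to 0.86). PRL, the MCM7 subunit of the replication helicase, differed by -0.17 (-0.77 to 0.43). The auxin response genes WES1 (GH3.5) and LBD16 differed by 0.16 (-0.39 to 0.71) and 0.13 (-1.06 to 1.32). The clock gene GI differed by -0.27 (-0.996 to 0.46) and AGL42, listed for the stem cell niche, by 0.063 (-0.58 to 0.71). For green tissue, RCA (Rubisco activase) and the light-harvesting protein gene LHCB4.1 differed by -0.50 (-1.46 to 0.45) and -0.36 (-1.26 to 0.53). EXPA7 and EXPA18, listed for root hair cells as well, differed by -0.39 (-1.04 to 0.27) and -0.19 (-0.68 to 0.30).

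Across all probe sets, limma called 0 of 13647 between treated and untreated roots at 120 min, with a lowest adjusted p of 0.999. At an unadjusted p under 0.05 there were 164 (86 higher and 78 lower in treated roots), against 682 expected by chance alone. The 2 groups did not overlap for 21.9% of probe sets, against 33.3% by chance. Both chance values take the arrays as exchangeable, while an offset went with the replicate number. In 50 simulated draws with that offset as estimated and no change between groups, 126 probe sets had an unadjusted p under 0.05 on average (94 to 150) and 23.1% did not overlap (22.2 to 24). With the offset shrunk by the part that noise gives, these were 192 (156 to 223) and 25.2% (24.1 to 26.1). The median half-width of the 95% confidence interval was 0.64 in log2.

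The 24 named genes with the smallest unadjusted p (0.00548 to 0.0213) and groups that did not overlap held 12 with higher and 12 with lower signals in treated roots. None passed the adjustment (adjusted p = 0.999 for each), so they are values, not changes. AT1G32580 read 135 ± 6.45 in treated and 64.2 ± 14.6 in untreated roots. AT5G46920, an intron maturase, read 125 ± 29.7 and 62.4 ± 3.12, and WRKY22, a transcription factor of defence responses, read 55.0 ± 10.7 and 25.4 ± 3.58. GH9C3, of the glycosyl hydrolase 9 family, read 66.3 ± 18.7 and 31.5 ± 4.15. In untreated roots at 0 min these genes read 104 ± 22.6, 74.95 ± 25.9, 39.7 ± 2.05 and 58.15 ± 6.69, in the order given. The 0 min arrays of GH9C3 overlapped the treated ones. The other genes with higher values were AT2G18890, AT3G53470, AT1G50910, AT4G17310, AT5G35660, AT4G04750, AT5G24130 and AT1G69360, and the 12 log2 differences ran from 0.73 to 1.32. AT5G12110, a subunit of translation elongation factor 1B, read 44.55 ± 3.89 in treated and 95.7 ± 1.75 in untreated roots at 120 min, and 49.1 ± 12.7 in untreated roots at 0 min. The extensin-like gene AT3G54580 read 274 ± 117 in treated and 514.5 ± 104 in untreated roots at 120 min. The homeobox gene HAT3.1 read 25.3 ± 19 and 66.85 ± 10.8. At 0 min AT3G54580 and HAT3.1 read 511 ± 103 and 64.5 ± 17.7 (SD, n = 2 for each). The remaining genes with lower values were AT2G23700, AT2G21860, AT1G35220, AT3G18170, AT2G34310, AT5G51180, AT5G51980, AT1G04945 and AT3G58510, and the 12 differences ran from -1.20 to -0.66. Except for AT5G12110 and AT3G18170, each of the 12 read lower on treated replicate 1 than on treated replicate 2. AT3G54580 read 191 and 357 on these arrays, and HAT3.1 read 11.85 and 38.7.

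The second comparison followed untreated roots from 0 to 120 min, as the untreated control for time. The wall-modifying enzyme gene XTH18 read 214 and 389 on the untreated arrays at 120 min and 100.4 and 139.9 at 0 min, a 2.27-fold higher mean on the log2(signal + 16) scale. The related XTH19 read 197 ± 11.7 at 120 min and 117 ± 0.569 at 0 min (SD, n = 2 for each). Both passed when adjusted over the list alone (limma adjusted p = 0.0362 and 0.0463), as 2 of the 8 XTH members, and 0 passed over all genes. Adjustment over a list alone was made in each of the 6 tested lists and was not corrected for their number. The log2 difference of XTH18 was 1.18 and ranged from 0.77 to 1.59 with each array left out. Neither passed over the list without untreated 0 min replicate 1 (adjusted p = 0.25 for each), 0 min replicate 2 (0.0733 and 0.259) or 120 min replicate 2 (0.199 for each), nor with eBayes without a trend (0.0509 and 0.0671). XTH19 also did not pass without 120 min replicate 1 (0.122) and under quantile normalization (0.0533). AT2G38870, a protease inhibitor of the potato inhibitor I type, read 829.5 ± 53.9 at 120 min and 406 ± 99.1 at 0 min. Hop3, a co-chaperone of Hsp70 and Hsp90, read 99.7 ± 3.36 and 43.0 ± 14.5, and AT5G51440, a small heat shock protein, read 57.7 ± 21 and 11.1 ± 10.2. BCAT4, an enzyme of methionine chain elongation in glucosinolate synthesis, read 143 ± 111 and 42.5 ± 0.78.

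Across all probe sets limma called 0 of 13647 between 120 and 0 min, with a lowest adjusted p of 1. At an unadjusted p under 0.05 there were 158 (93 higher and 65 lower at 120 min), against 682 expected by chance, and the groups did not overlap for 27% of probe sets, against 33.3% by chance. The draws with the replicate offset gave 127 (106 to 149) and 23.1% (22.2 to 23.8), and with the shrunk offset 193 (170 to 217) and 25.2% (24.3 to 26.1). The count of 158 thus lay above the first range and below the second, and the 27% above both. These ranges leave out variation shared between probe sets. The 24 named genes (unadjusted p from 0.00411 to 0.0249, adjusted p = 1 for each) held 20 with higher and 4 with lower values at 120 min. Besides the genes above, values were higher for the expansin EXPA15 by 1.13, the AGC kinase WAG2 by 1.11 and the subtilase SBT3.5 by 1.00 in log2. With each array left out these ranged from 0.49 to 1.78, from 0.65 to 1.57 and from 0.53 to 1.47, and BCAT4 from 0.46 to 2.02. They were also higher for AT3G16220, AT1G53620, AT5G50140, AT1G66880, AT1G67800, AT5G12110, AT1G20823, AT3G07600, AT1G05340, AT1G51850 and AT5G55050, and the 20 log2 differences ran from 0.68 to 1.57. AT1G17490 read 167 ± 3.31 at 120 min and 320 ± 1.01 at 0 min, a log2 difference of -0.88. AT4G24100, AT1G60200 and AT1G63980 differed by -0.99, -0.77 and -0.63.

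**Figure D3:**
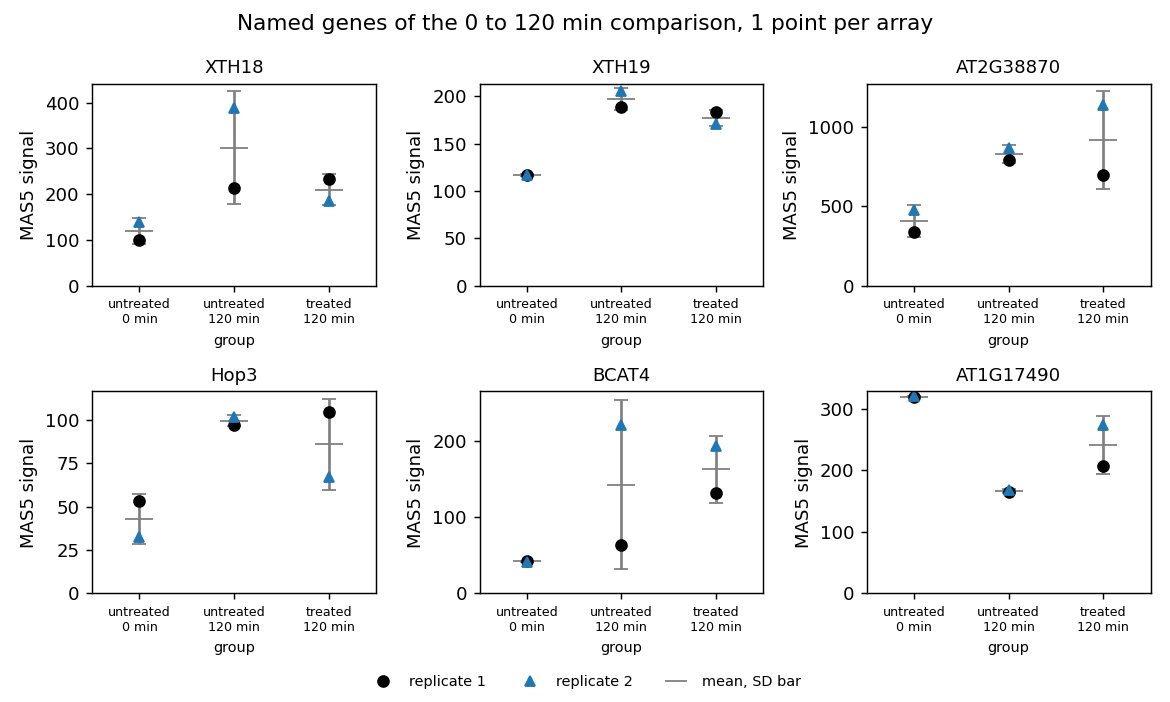
MAS5 signal (vertical axes, linear, starting at 0) of 6 genes named in the comparison of 120 with 0 min, in the 3 groups, with 1 point per array and a bar for the mean and SD of 2 arrays. XTH19 read 117 and 116.5 at 0 min, 189 and 205 in untreated roots at 120 min and 183 and 171 in treated roots.

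Camera called 0 of the 6 tested lists between 0 and 120 min, with 1 at an unadjusted p under 0.05 (touch and wound response), and with an estimated correlation it called 0, as fry did, both with 0 at an unadjusted p under 0.05. The XTH family had 4 members higher and 4 lower, a median of 0.00955 and a mean of 0.17 (camera adjusted p = 0.169), and XTH32 and XTH20 differed by -0.27 and -0.25. With the filter at the 60th percentile that family had a mean of 0.31 (adjusted p = 0.0155). Touch and wound response genes had 3 members higher (mean 0.33, adjusted p = 0.169), with STZ at 0.42, CML38 at 0.325 and WRKY53 at 0.23. Alpha-expansins had 1 member higher and 5 lower, so that their median was -0.115 and their mean 0.092 (adjusted p = 0.523). That mean turned to -0.12 without untreated 0 min replicate 1 (adjusted p = 0.569) and to -0.26 without untreated 120 min replicate 2 (adjusted p = 0.588). EXPA7, EXPA9, EXPA18 and EXPA20 differed by -0.13, -0.10, -0.023 and -0.15. GA perception genes had a mean of -0.28 (adjusted p = 0.418), with SLY1 at -0.29, GID1B at -0.43 and GID1A at -0.10, and the DELLA-induced genes, XERICO (-0.49) among them, had a mean of -0.34 (adjusted p = 0.242). The kinase inhibitors had a mean of -0.13 (adjusted p = 0.501), with SMR2 at -0.44, SIM at 0.18 and SMR3 at -0.13. Without untreated 0 min replicate 1, the touch list had a mean of 0.465 (adjusted p = 0.0226) and the DELLA-induced list one of -0.58 (adjusted p = 0.0499). Without untreated 0 min replicate 2 they were 0.186 and -0.10 (adjusted p = 0.525 and 0.846), and without untreated 120 min replicate 2 they were 0.157 and -0.165 (adjusted p = 0.588 for each). As values, GASA7 differed by -0.15, GASA10 by 0.25, AUR1 by -0.043, AUR2 by -0.25, PRL by -0.011, LBD16 by 0.87, WES1 by -0.093, GI by -0.033, RCA by 0.22, LHCB4.1 by 0.20 and AGL42 by 0.086. That of LBD16 ranged from 0.168 to 1.57 with each array left out. Those of AUR1, PRL, GI and EXPA18 turned positive under median centring.

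The third comparison set treated roots at 120 min against untreated roots at 0 min, and so held time as well as treatment. BCAT4 read 163 ± 43.8 in treated roots and 42.5 ± 0.78 at 0 min, and AT5G39580, a peroxidase, read 124 ± 87.6 and 26.6 ± 8.59 (SD, n = 2 for each). AT3G45160 and AT1G53620 were the other genes with the largest higher values, by 1.93 and 1.78 in log2. The largest lower values were those of AT2G07708 (-1.83), the plastid gene accD (-1.40), which encodes a subunit of acetyl-CoA carboxylase, AT5G24620 (-1.35) and AT4G00990 (-1.31). In each of these 4, treated replicate 1 read lower than treated replicate 2, as for AT2G07708 with 67.9 and 348. None of the 8 passed (adjusted p = 1 for each).

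Limma called 0 of 13647 probe sets in this comparison, with a lowest adjusted p of 1. At an unadjusted p under 0.05 there were 350 (195 higher and 155 lower in treated roots), against 682 expected by chance, and the groups did not overlap for 27.9% of probe sets, against 33.3% by chance. The draws with the replicate offset gave 128 (104 to 155) and 23.2% (22.5 to 24), and with the shrunk offset 193 (158 to 221) and 25.2% (24.5 to 26.2). Both observed values lay above these ranges. The draws left out variation shared between probe sets and gave every array the same spread. The SD of the replicate difference was 0.60 in treated and 0.40 in 0 min roots. The ranges are thus too narrow a measure of chance, and the excess decides nothing. Without treated replicate 2, 6 probe sets passed, all lower, among them AT2G07708 and accD (adjusted p = 0.0361 for each), and treated replicate 1 was then the only treated array.

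The 24 genes named for time in untreated roots were set against their values in treated roots. The difference from 0 min had the same sign in treated roots for 23 of the 24, and for 21 both treated arrays lay outside the range of the 0 min arrays on the same side. Both comparisons used the same 0 min arrays and the genes had been chosen by their p. In 50 simulated draws with no change in any group, the same selection gave 22.4 genes of the same sign on average (20 to 24) and 16.6 outside the range (11 to 21). The 23 lay within its range and the 21 at the top of its own. These ranges hold the selection and the shared 0 min arrays without any effect. The 0 min group was too small to be split into parts of 2 arrays each.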

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

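The screen of control probe sets was chosen after the data had been seen. A control probe set for the 3' end of ubiquitin, outside the comparisons, read higher on both treated arrays (2745 and 2678) than on each of the 4 untreated arrays, the highest of which read 2467.5. It was 1 of 35 control probe sets with a mean above the signal filter. Chance alone puts both treated arrays above the other 4 in 6.67% of probe sets, so this 1 is no more than chance gives. No explanation was tested for it.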

How the results depend on the processing

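Array weights and the plastid and WRKY sets were chosen only after the results were seen, and the other alternatives before. Limma called 0 probe sets in each of the 3 comparisons under every alternative other than leaving out an array, with 62 to 924 at an unadjusted p under 0.05. Leaving out each array in turn gave 0 to 6 calls for treated roots against 0 min (6 without treated replicate 2, where 1718 had an unadjusted p under 0.05) and 0 for the other comparisons, with at least 47 at an unadjusted p under 0.05. A group left with 1 array was assumed to vary like the other groups. Array weights did not move the mean difference of any list, since 2 arrays cannot be told apart in weight within a group. Camera has no robust option, so the lists have no value with robust eBayes. Low signals near the background limit what MAS5 values can show.

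With the replicate number as a block, limma also called 0 probe sets in each comparison, with 446, 417 and 804 at an unadjusted p under 0.05 in the order of the report and lowest adjusted p-values of 0.998, 0.676 and 0.536. The replicate differences of the 3 groups correlated at 0.306, 0.365 and 0.342 across probe sets. The control ratios and spikes also went with the number. The labels name no shared batch and there were 2 numbers only, so the numbers were not taken to pair the arrays, and what they mark stays unknown. The block changed no list call, with 1 list past the threshold for treated roots at 120 min (alpha-expansins, adjusted p = 0.0159) and 0 between 0 and 120 min.

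For treated against untreated roots at 120 min, the count of 1 list by camera became 0 with an estimated correlation, pseudocount 1, no filter, quantile normalization and median centring, with 0 or 1 list at an unadjusted p under 0.05, and ranged from 0 to 4 with each array left out. Between 0 and 120 min the count of 0 lists became 1 with the filter at the 60th percentile, where fewer lists were tested, and ranged from 0 to 2 with each array left out. The mean of the alpha-expansins ranged from -0.68 to 0.024, of GA perception from -1.21 to 0.615, of DELLA-induced genes from -1.14 to 0.555 and of the XTH family from -0.25 to 0.018 in treated roots at 120 min. The touch list ranged from 0.101 to 0.50 and the kinase inhibitors from 0.068 to 0.25. Between 0 and 120 min the alpha-expansins ranged from -0.26 to 0.45, the touch list from 0.157 to 0.49, the DELLA-induced genes from -0.58 to -0.10, GA perception from -0.50 to -0.053, the XTH family from 0.031 to 0.30 and the kinase inhibitors from -0.22 to -0.044. The cause of these turns was not tested beyond the array left out.

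Only the pseudocounts, quantile normalization and median centring could change the log2 difference of a gene. The other settings could not turn a sign, and no named gene had passed in the main fit. Of 1296 values of named genes under all of these settings, 1289 kept their direction and side of the threshold and 7 turned sign. The 1296 thus hold many values whose direction was fixed in advance. In treated roots at 120 min, GASA10 was -0.0092 under quantile normalization and -0.0068 under median centring, and GASA7 was -0.0033 under median centring. Between 0 and 120 min under median centring, AUR1 was 0.00065, PRL 0.032, GI 0.010 and EXPA18 0.021. The cause was not tested. With each array left out, 47 of 672 values turned sign. Leaving out an array of the group outside a comparison could not change its log2 differences, so the 672 hold many values that could not turn. Of the genes named by p or size, 7 of 24, 12 of 24 and 5 of 8 in the 3 comparisons moved by over 1.5 times with an array left out. Their sign could not turn, since they were chosen for groups that did not overlap, so the 0 that turned is no sign of stability. Of the genes named from lists only, 28 of 29 in treated roots at 120 min and 25 of 27 between 0 and 120 min moved by as much or turned sign.

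For treated roots at 120 min these ranged for GID1A from -0.81 to 0.29, GID1B from -2.29 to 1.18, SLY1 from -0.52 to 0.38, XERICO from -0.40 to 0.29, GASA7 from -0.28 to 0.40, GASA10 from -0.19 to 0.29 and EXPA15 from -1.035 to 0.25. They ranged for AUR2 from -0.16 to 0.57, AUR1 from -0.040 to 0.36, PRL from -0.37 to 0.024, SIM from -0.19 to 0.073, WES1 from -0.059 to 0.37 and LBD16 from -0.31 to 0.58. The ranges were -0.71 to 0.17 for GI, -1.11 to 0.10 for RCA, -0.95 to 0.23 for LHCB4.1 and -0.25 to 0.38 for AGL42.

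Between 0 and 120 min they ranged for GID1A from -0.44 to 0.24, GASA7 from -0.41 to 0.11, EXPA7 from -0.39 to 0.13, EXPA9 from -0.27 to 0.073, EXPA20 from -0.62 to 0.32 and EXPA18 from -0.098 to 0.052. The ranges were -0.61 to 0.067 for XTH32, -0.91 to 0.42 for XTH20, -0.16 to 0.075 for AUR1, -0.23 to 0.21 for PRL, -0.36 to 0.092 for SMR3 and -0.31 to 0.12 for WES1. They were -0.11 to 0.96 for STZ, -0.0043 to 0.65 for CML38, -0.24 to 0.17 for GI, -0.39 to 0.82 for RCA, -0.39 to 0.79 for LHCB4.1 and -0.23 to 0.40 for AGL42.

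Several settings, and leaving out an array of the group outside a comparison, could not move the mean difference of a set. The plastid and WRKY sets kept their direction in all 36 values under other settings and in all 18 with an array left out. Their unadjusted camera p crossed 0.05 in 5 of the 36, among them all 3 values with an estimated correlation, and in 4 of the 18.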

Other observations

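The screen of gene families and plastid genes and the tests of 3' bias and of the plastid set without 1 array were chosen after the result was seen. The correlation on arrays that do not overlap and the replicate block of the plastid set were fixed before their values were seen.

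Plastid-encoded transcripts, which code for parts of photosynthetic complexes and of the plastid's own expression machinery, were lower in treated roots by value. Of 53 tested probe sets for plastid genes, 38 were lower and 15 higher than in untreated roots at 120 min, with a mean log2 difference of -0.28 (camera adjusted p = 6.02e-06 over 31 sets screened). With an estimated correlation the adjusted p was 0.911, and 0 of the 53 passed by themselves. Against 0 min the mean was -0.35, with 42 lower (adjusted p = 2.04e-05, and 0.948 with an estimated correlation), and without treated replicate 1 it was -0.078 (adjusted p = 0.707). At 120 min the log2 differences of the members ran from -1.04 for accD to 0.42 for ndhC.

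Among nuclear families, 5 WRKY transcription factors (WRKY6, WRKY20, WRKY22, WRKY47 and WRKY53) had 4 members higher and 1 lower in treated roots at 120 min, with a mean of 0.29. The camera p was 0.0153, and 0.158 after adjustment over 31 sets, or 0.911 with an estimated correlation. Without treated replicate 1 the mean was 0.54, and without treated replicate 2 it was 0.046, with 1 treated array left in each case. The expansin family, with the same 6 members as the fixed list, had the smallest p of the nuclear families (adjusted p = 0.0726 over 31 sets, 0.0411 with the replicate number as a block and 0.783 without treated replicate 1). Against 0 min, the UGT glycosyltransferases (22 members) had a mean of -0.015 (camera adjusted p = 0.897, or 0.948 with an estimated correlation). Without treated replicate 1, which left 1 treated array, their mean was 0.275 and that of WRKY was 0.44. WRKY53 read 48.2 and 85.0 in treated roots and 43.5 and 43.0 in untreated roots.

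A candidate explanation for the lower plastid signals is that they come from treated replicate 1 alone. The mean log2 signal of the 53 probe sets was 7.30 on that array, 7.84 on treated replicate 2 and 7.72 to 7.98 on the 4 untreated arrays. Without that array the mean difference was -0.014 and the camera p 0.52 (0.783 after adjustment). This follows from the array means that prompted the explanation, so it describes where the difference lies and is no separate support. Each group held both replicate numbers. A technical split by number that was equal in all groups therefore cancels and cannot give the mean difference. The set passed with that number as a block (camera adjusted p = 2.43e-06 over 31 sets, 7.84e-08 before adjustment). The block could not move the mean difference, so that pass decides nothing. A split that differed between the groups stays open. The mean of replicate 1 minus replicate 2 was 0.027 at 0 min, -0.255 in untreated and -0.54 in treated roots at 120 min. Treated replicate 1 also had the lowest 25S ribosomal RNA signal, 61.3 against 812 to 5288 on the other arrays. Untreated 120 min replicate 1 was the next lowest for both, at 812 and 7.72. The actin 3' to 5' ratio of treated replicate 1 was the highest, 14.8 against 2.22 to 4.94. Whether array quality lowered the plastid signals was not tested and stays open. A response to GA or a difference in plant line stays open as well and was not tested. Either would have to differ between the 2 treated arrays.

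Treated replicate 1 stood apart from the other 5 arrays. Its 3' to 5' ratio was the highest for 3 of 3 control genes. The ratios measure 3' bias, so a stronger 3' bias of its control transcripts was seen directly. Whether that bias explains why the array stood apart stays open, since these ratios were seen before the explanation was put. The treated minus untreated differences of replicate 1 and of replicate 2 correlated at -0.132 across 13647 probe sets, which are not independent replicates. A difference between the 2 root samples in tissue or response stays open, as untested.

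A response to time or handling may be shared by treated and untreated roots. On arrays that did not overlap, the 0 to 120 min difference of untreated roots correlated with that of treated roots at 0.0193 in one pairing and at 0.191 in the other, across 13647 probe sets. A shared response was to give more than 0.1 in both pairings and its absence 0 or less in at least 1, so the test decided neither way. The second pairing holds treated replicate 1. In simulated draws without any change and with the replicate offset shrunk, 24.3% to 26.1% of probe sets did not overlap between 0 and 120 min, below the 27% seen. In these draws 170 to 217 had an unadjusted p under 0.05, above the 158 seen. With the offset as estimated the ranges were 22.2% to 23.8% and 106 to 149, both below the values seen. The draws gave every array the same spread, which the first treated array did not have. They also left out variation shared between probe sets, so a response to time stays open.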
